A study of Mus musculus with 6 samples.

How the data were processed

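RNA from 6 livers of C57BL/6 mice was profiled, 3 wild type and 3 deficient in Mettl3, the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on RNA. Per the labels' protocols, livers were flash frozen, total RNA was extracted with TRIzol, ribosomal RNA was removed with Ribo-Zero Gold and directional libraries were made with the NEBNext Ultra II kit. Per the submitters' processing notes, the authors used HISAT2, featureCounts and the mouse build mm10; versions, settings, annotation and the strand setting of the counting are not given in the sources used here. The deposited values are raw counts per gene under NCBI Entrez identifiers, with no normalization, for 27179 genes in each library. The age and sex of the animals, the hour of collection and how Mettl3 was made deficient are also not given in the sources used here. The labels count livers and do not say more of the animals, so p-values measure the spread between these 6 samples.

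Gene symbols and coordinates came from the RefSeq annotation of GRCm38.p6, the same build as mm10, and 25275 of the 27179 identifiers matched. Counts cover whole genes, so if only part of a gene is deleted, reads from the rest still count. Where strand was not used in counting, reads of overlapping antisense genes could not be told apart. Reads of near-identical genes (the major urinary protein, Serpina1, Cyp3a41, Cyp4a12, Cyp2c, Gsta1, Hba-a and Acot1 and Acot2 genes) can be split between copies, and their values are uncertain.

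Groups were taken from the genotype labels. Counts were tested with edgeR 4.0.16 (R 4.3.3) by its robust quasi-likelihood F test, two-sided, with TMM factors, an intercept and the group as the design, and filterByExpr with a minimum count of 10 and a minimum total of 15, which kept 14380 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Each adjusted p of a gene comes from this edgeR test unless another tool is named. Levels are TMM-normalised CPM values (counts scaled to a common library size), given as mean ± SD with n = 3 per group. Standard errors of log2 fold changes were derived from the fold change and the F statistic. All fold changes are Mettl3-deficient against wild type. For a gene without counts in a group, a bound was computed against a floor of 3 counts over the group, which covers counting error only.

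The 36 gene lists, the test, the covariates, the alternatives and the rule for the genes named in the text were fixed before the data were examined. The lists held 694 members, of which 692 were in the files. Lists with at least 5 tested members (35 of the 36) were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, with camera and an estimated correlation, and with fry, each adjusted over the lists. Beside the calls over all genes, members were also counted with p adjusted over the list alone. The text names every tested member of the m6A machinery, the 12 largest and the 12 smallest log2 fold changes among called genes with a mean CPM of at least 5 and no overlap between the groups, the 6 smallest p-values in each direction, up to 4 members of each list by p, and the sex chromosome genes, 180 genes in all. In the 12 and the 6, symbols of unnamed gene models (Gm followed by a digit, or ending in Rik) were left out. Any other gene named was chosen after its values were seen.

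Depth ran from 31960205 to 36025772 counts per library. Counts were simulated from these libraries for the same comparison over 14380 genes. In them, 80% of 100 genes changed 4-fold and 18% of 100 genes changed 2-fold were called, with 4 unchanged genes called. Changes near 2-fold were often missed there, but few genes were changed. The real comparison called 3420 genes, 2139 of them changed more than 2-fold. So many calls admit larger unadjusted p-values at the same adjusted p, and the simulated rates need not hold for it. No 2 libraries were alike within sampling noise: the chi-square per degree of freedom between libraries of a group was 17.1 or more.

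Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of CPM of at least 1 in 3 samples, the replicate number as a block, removal of the 20 most abundant genes, and each library left out in turn. Scaling by library size alone, with no composition factors, and a covariate for libraries with more than 100 counts of Y-linked genes were added after seeing the data.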

Results

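The series compared gene expression in wild-type and Mettl3-deficient livers. RNA-seq counts were obtained from 3 wild-type and 3 Mettl3-deficient mouse livers. The wild-type libraries held 31960205, 34297553 and 32212085 counts and the Mettl3-deficient libraries 34576824, 36025772 and 35263636 counts. The first principal component of log2 CPM held 61.1% of the variance and separated the genotypes. The second held 20.2% and set wild type replicate 1 apart, whose correlation with the other wild-type libraries, across genes, was 0.943 and 0.939, against 0.983 between those libraries. Y-linked transcripts were present in wild type replicate 1 and in Mettl3-deficient replicates 1 and 2, with 6508, 4747 and 5031 counts, and had 0 counts in the other libraries.

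Mettl3 (Entrez 56335, chromosome 14, 52294841 to 52308741, GRCm38) fell from 13.2 ± 1.09 CPM in wild-type livers to 5.83 ± 0.836 CPM in Mettl3-deficient livers (SD, n = 3). The 3 wild-type libraries held 13.4, 14.3 and 12.1 CPM of Mettl3 and the 3 Mettl3-deficient libraries 5.96, 6.60 and 4.94 CPM. The log2 fold change of Mettl3 was -1.18 ± 0.20 (SE), with an edgeR adjusted p of 0.00797. Among the other m6A genes, the m6A readers Ythdf2 and Ythdf1 rose, Ythdf2 from 27.9 ± 3.56 to 89.6 ± 11.6 CPM (log2 fold change 1.69 ± 0.17, edgeR adjusted p = 0.0015) and Ythdf1 from 26.4 ± 2.53 to 48.6 ± 6.56 CPM (0.88 ± 0.16, edgeR adjusted p = 0.00992). Cbll1, a component of the writer complex, rose by 0.58 ± 0.15 on the log2 scale (edgeR adjusted p = 0.0311).

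The other 15 of 19 tested m6A genes were not called, and the same 3 rose and 1 fell with p adjusted over the list alone. Mettl14, the partner of Mettl3, had a log2 fold change of 0.40 (edgeR adjusted p = 0.153) and Wtap one of 0.45 (edgeR adjusted p = 0.062). The values were 0.53 for Rbm15, 0.71 for Mettl16, 0.16 for Virma, 0.16 for Fto, 0.27 for Hnrnpa2b1, 0.25 for Ythdc1, 0.07 for Ythdf3 and -0.31 for Alkbh5. Those of Rbm15b (0.0087), Zc3h13 (-0.09), Ythdc2 (-0.04), Igf2bp2 (-0.14) and Igf2bp3 (-0.06) were near 0. The call of Cbll1 was lost when wild type replicate 2 or 3 or any Mettl3-deficient replicate was left out, with the highest edgeR adjusted p at 0.109. Scaling by library size alone moved the median log2 fold change of all tested genes from 0.01 to 0.49, gave -0.70 for Mettl3 and 12 higher m6A genes, and turned Alkbh5, Zc3h13, Ythdc2, Igf2bp2 and Igf2bp3 to values above 0.

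Large changes ran in both directions. Ly6d (Entrez 17068, chromosome 15, 74762056 to 74763567), a surface protein of the Ly6 family, rose from 0.264 ± 0.0453 to 173 ± 34.3 CPM (SD, n = 3), 648-fold, with an edgeR adjusted p of 1.32e-05. Cd36, a fatty acid uptake receptor (Entrez 12491, chromosome 5, 17781690 to 17888959), rose from 21.1 ± 0.566 to 196 ± 24.3 CPM, and the sphingomyelinase gene Smpd3 from 3.55 ± 0.648 to 31.5 ± 2.54 CPM. Crp, which encodes C-reactive protein (Entrez 12944, chromosome 1, 172698056 to 172699966), fell from 553 ± 0.357 to 53.6 ± 12.1 CPM. Sult5a1, a sulfotransferase, fell from 15.7 ± 2.96 to 0.121 ± 0.0674 CPM, and the pseudogene Serpina4-ps1 from 77.4 ± 19.1 to 0.0978 ± 0.0873 CPM.

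In all, 3420 of 14380 tested genes were called by edgeR at an adjusted p under 0.05, with 1906 higher and 1514 lower in Mettl3-deficient livers. Of these, 2139 changed more than 2-fold, 1306 of them higher and 833 lower. The 12 genes with the largest positive fold changes were Sprr1a, Ly6d, Bex2, Phlda2, Gsta1, Nupr1, Igdcc4, Tgm7, Psat1, Msantd3, Rin1 and Trib3. Sprr1a had 0 counts in every wild-type library and 18.2 ± 14 CPM in Mettl3-deficient livers, at least 507-fold higher. Its call was lost when wild type replicate 2 or 3 or Mettl3-deficient replicate 1 or 2 was left out, those of Bex2, Nupr1 and Trib3 without wild type replicate 2 or 3 or Mettl3-deficient replicate 1, and those of Psat1 and Rin1 without wild type replicate 2 or 3. The 12 genes with the largest negative fold changes held 8 major urinary protein genes (Mup2, Mup3, Mup9, Mup10, Mup13, Mup16, Mup18 and Mup22), near-identical copies whose reads can be split between them, with Serpina4-ps1, Serpina12, Serpina1e and Sult5a1. Of these, Mup9, Mup13, Mup16, Mup18 and Serpina12 lost their call when any 1 Mettl3-deficient replicate was left out, Mup2 without Mettl3-deficient replicate 2, Mup9, Mup16 and Mup18 also without wild type replicate 2, and Mup16, Mup18 and Serpina12 also without wild type replicate 3. The remaining genes among the 6 smallest p-values in a direction were Hr, Phlda3, Smim10l1 and Abca8a, and Hr rose 24.8-fold while Smim10l1 fell from 90.7 ± 8.84 to 14 ± 1.21 CPM. When wild type replicate 2, wild type replicate 3, Mettl3-deficient replicate 1 or Mettl3-deficient replicate 2 was left out, 1425, 1542, 1382 and 1859 genes were called, and 1072 of the genes were called in each of the 6 fits that left out 1 library. With library size alone, 89.0% of calls were higher, against 55.7% with TMM.

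**Figure D1:**
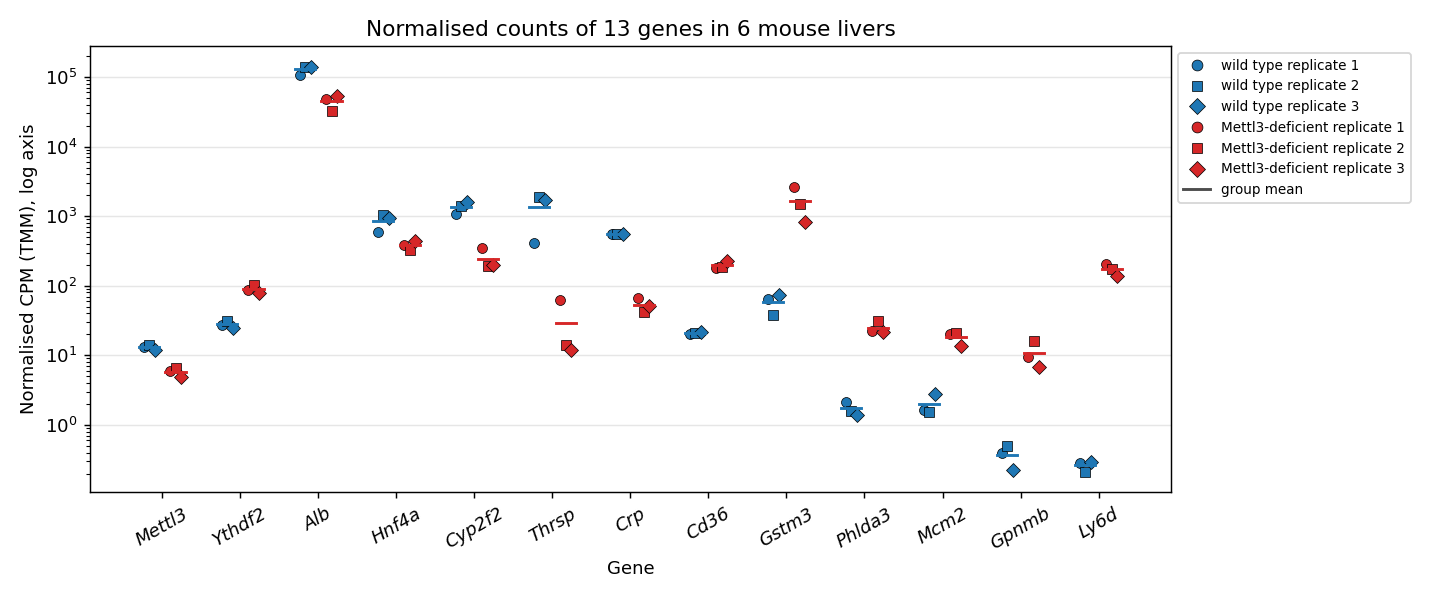
Normalised CPM (TMM, log axis) of 13 genes in each of the 6 livers, with blue for wild type, red for Mettl3-deficient, symbols for replicates and bars for group means. Mettl3 lies between 12.1 and 14.3 CPM in wild-type livers and between 4.94 and 6.60 CPM in Mettl3-deficient livers, and Ly6d has group means of 0.264 and 173 CPM.

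Some genes of hepatocyte identity and secretion were lower. Of 26 tested genes for hepatocyte secreted proteins, 9 fell and 0 rose (17 fell adjusted over the list alone). Apoc3, an apolipoprotein of triglyceride-rich particles, fell from 2882 ± 181 to 1048 ± 234 CPM (SD, n = 3; edgeR adjusted p = 0.0104), and Rbp4, F9 and Fgb fell 2.62-, 2.41- and 2.26-fold. Of 20 hepatocyte transcription factors, 8 fell and 0 rose (9 fell adjusted over the list alone), among them Onecut2 from 111 ± 1.52 to 47 ± 15.7 CPM and Hnf4a, a central regulator of hepatocyte genes, from 857 ± 231 to 382 ± 55.8 CPM. Cebpa and Nr1h4, the bile acid receptor, fell 2.65- and 2.47-fold.

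The medians of the secreted protein and transcription factor lists were -0.84 and -0.62 on the log2 scale (-0.38 and -0.14 with library size alone). Camera gave adjusted p-values of 2.2e-05 and 0.0009, and both calls were lost with an estimated correlation (adjusted p = 0.542 for each). Only Apoc3 in the first list and Onecut2 in the second are among the 4 genes named for each list that were called in every fit that left out 1 library. The number of secreted protein genes that fell was 2, 4 and 1 without wild type replicate 2, wild type replicate 3 and Mettl3-deficient replicate 1, and 18 with DESeq2. For the transcription factors it was 1, 2, 2 and 2 without those libraries and Mettl3-deficient replicate 2, and 4 with library size alone.

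Lipid genes moved in both directions. In fatty acid and triglyceride synthesis, 9 of 20 genes fell and 0 rose (11 fell adjusted over the list alone). Thrsp, a regulator of lipogenesis, fell from 1332 ± 802 to 29.3 ± 28.3 CPM (SD, n = 3; edgeR adjusted p = 0.0099), and Acss2, Srebf1 and Mlxipl, the latter pair transcription factors of lipogenesis, fell 4.19-, 3.75- and 3.19-fold. In cholesterol synthesis, 8 of 25 genes fell and 0 rose, the same numbers as adjusted over the list alone, with Tm7sf2 from 232 ± 34.5 to 57.2 ± 29 CPM and Stard4, Idi1 and Insig1 lower by 2.98-, 2.78- and 3.65-fold. Of 24 genes of fatty acid oxidation and PPARalpha targets, 6 rose and 2 fell, likewise adjusted over the list alone. Acot2, a mitochondrial acyl-CoA thioesterase, rose from 3.69 ± 1.96 to 89.9 ± 11 CPM, Ehhadh, a peroxisomal oxidation enzyme, from 284 ± 59.9 to 1194 ± 447 CPM, and Vnn1 and Cidec, a lipid droplet protein, rose 3.03- and 2.82-fold.

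The medians were -1.09 for fatty acid synthesis, -0.81 for cholesterol synthesis (-1.29 without Mettl3-deficient replicate 1) and 0.33 for oxidation (0.19, 0.60 and 0.044 without wild type replicate 1, Mettl3-deficient replicate 2 and Mettl3-deficient replicate 3), and with library size alone they were -0.62, -0.34 and 0.79. Camera called the first pair (adjusted p = 2.2e-05 each) and not the oxidation list (adjusted p = 0.063). The oxidation list was called without a filter on low counts (adjusted p = 0.0352), with the replicate block (0.0463) and the Y-linked covariate (0.0021), and without wild type replicate 1 (0.0456), wild type replicate 3 (0.0206) or Mettl3-deficient replicate 2 (0.00365). With an estimated correlation the 3 lists had adjusted p = 0.283, 0.542 and 0.709. Cholesterol genes that fell numbered 2 without wild type replicate 2, wild type replicate 3 or Mettl3-deficient replicate 2, 4 without Mettl3-deficient replicate 3, 14 without Mettl3-deficient replicate 1 and 4 with library size alone. Fatty acid synthesis genes that fell numbered 4 without wild type replicate 2, wild type replicate 3 or Mettl3-deficient replicate 2 and 5 without Mettl3-deficient replicate 1, and with library size alone 11 oxidation genes rose.

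Some genes of bile acid, glucose and amino acid metabolism were lower. The bile acid uptake transporter Slc10a1 fell from 802 ± 218 to 139 ± 66.1 CPM (SD, n = 3; edgeR adjusted p = 0.00886), and Slco1a1, Cyp27a1 and Abcg8 fell as well, so that 6 of 20 bile acid genes fell and 1 rose (6 and 1 adjusted over the list alone). In glucose and glycogen metabolism 6 of 18 genes fell and 1 rose (10 and 1 adjusted over the list alone), including the glycolytic enzyme Pklr, the glycogen synthase Gys2 and the growth factor Igf1, lower by 2.95-, 3.14- and 2.64-fold. In the urea cycle and amino acid list 12 of 26 genes fell and 0 rose (16 adjusted over the list alone). Prodh, which oxidises proline, fell from 394 ± 118 to 116 ± 9.63 CPM, Gnmt from 2517 ± 410 to 817 ± 308 CPM, and Otc and Sds fell 2.57- and 4.09-fold.

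Camera adjusted p-values for these 3 lists were 0.000605, 0.00134 and 2.2e-05, and each call was lost with an estimated correlation (adjusted p = 0.542 for each). Genes that fell numbered 2, 1 and 2 in the 3 lists without wild type replicate 2, 2, 1 and 4 without wild type replicate 3, and 3, 2 and 1 without Mettl3-deficient replicate 1. Without Mettl3-deficient replicate 2, 7 amino acid genes fell, and with library size alone 3 bile acid genes rose.

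Some drug metabolism and zonated hepatocyte genes fell and fewer rose. Of 30 drug metabolism genes 14 fell and 3 rose (19 and 3 adjusted over the list alone). Cyp2f2, a periportal cytochrome P450, fell from 1356 ± 257 to 246 ± 85.5 CPM (SD, n = 3; edgeR adjusted p = 0.00384) and Cyp2c54 from 530 ± 46.5 to 13.2 ± 11.5 CPM. The glutathione transferases Gstm3 and Gsta1 rose, Gstm3 from 58 ± 18.1 to 1671 ± 920 CPM and Gsta1 from 0.558 ± 0.455 to 54.9 ± 28.6 CPM. Of 16 pericentral genes 5 fell and 1 rose, and of 17 periportal genes 6 fell and 2 rose (9 fell and 2 rose adjusted over the list alone, and the pericentral numbers did not differ). Glutamine synthetase (Glul), Gulo and Lect2 among pericentral genes fell 2.63-, 2.6- and 2.23-fold, Etnppl and Hal among periportal genes fell 3.62- and 1.89-fold, and Znrf3, a membrane regulator of Wnt signalling, rose 2.05-fold.

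The drug and periportal lists were called by camera (adjusted p = 0.000794 and 0.012) and lost with an estimated correlation (adjusted p = 0.542 each), and the pericentral list was not called (adjusted p = 0.113) except without wild type replicate 1 (0.0358) or Mettl3-deficient replicate 3 (0.0209). Pericentral genes that fell numbered 0 without wild type replicate 2, wild type replicate 3 or Mettl3-deficient replicate 1, and 1 without Mettl3-deficient replicate 2. With library size alone 1 fell, and with the replicate block 2 fell. Those that rose numbered 1 in the fits without 1 library, 3 with library size alone and 2 with the block. Lower calls thus did not outnumber higher calls in any of these. The list's median stayed below 0 without wild type replicate 2 (-0.59) and with the block (-0.66), against -0.68 in the main fit. Fewer calls there do not show that the shift was lost. Periportal genes that fell numbered 1, 2, 2 and 3 without wild type replicates 2 and 3 and Mettl3-deficient replicates 1 and 2, in that order. Drug metabolism genes that fell numbered 4, 6, 6 and 8 without those libraries, 9 without Mettl3-deficient replicate 3 and 8 with library size alone.

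Many cell cycle genes and p53 targets rose. Of 27 cell cycle genes 22 rose and 0 fell (23 rose adjusted over the list alone). Mcm2, a replication licensing factor, rose from 1.99 ± 0.714 to 18.2 ± 3.99 CPM (SD, n = 3; edgeR adjusted p = 0.00145), the spindle checkpoint kinase Bub1b from 0.803 ± 0.0215 to 6.9 ± 1.67 CPM, and Mcm4 and Aurka rose 4.23- and 4.06-fold. Of 22 p53 targets 13 rose and 0 fell (16 rose adjusted over the list alone), with Phlda3 from 1.72 ± 0.397 to 25.1 ± 5 CPM, Psrc1 from 0.181 ± 0.0675 to 7.6 ± 2.07 CPM, and Eda2r and Tnfrsf10b higher by 13.8- and 12.8-fold. Of 9 replication-dependent histone genes 0 rose and 2 fell, H3c14 and H2ac18, likewise adjusted over the list alone.

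The medians were 2.34 for the cell cycle list, 1.37 for p53 targets and -0.27 for histones, the last 0.19 with library size alone, 0.37 without a filter on low counts and 0.14, -0.09, -0.44 and -0.04 without wild type replicate 1, 2 or 3 or Mettl3-deficient replicate 2. Camera adjusted p-values were 2.18e-13, 8.05e-11 and 0.156, and with an estimated correlation the 3 lists had adjusted p = 0.405, 0.0972 and 0.55. Cell cycle genes that rose numbered 10, 11 and 14 without wild type replicate 2, Mettl3-deficient replicate 1 and Mettl3-deficient replicate 2. Of the 13 p53 targets, 12 were called in each fit that left out 1 library.

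Some genes of oxidative defence rose, and stress response genes went both ways. Of 21 NRF2 and glutathione genes 12 rose and 1 fell (12 and 3 adjusted over the list alone), with Cbr3, a carbonyl reductase, from 0.712 ± 0.33 to 19.3 ± 3.99 CPM (SD, n = 3; edgeR adjusted p = 0.000686) and Mgst3 from 13.5 ± 0.473 to 60.7 ± 8.69 CPM. The metallothionein genes Mt1 and Mt2 of this list had lower means, from 747 to 28.8 and from 342 to 6.03 CPM. They were not called (edgeR adjusted p = 0.0515 and 0.0615). In the unfolded protein and integrated stress response list 5 of 22 rose and 2 fell, likewise adjusted over the list alone. Those that rose were Atf3, Trib3, Psat1, Fgf21 and Nupr1, and Fgf21, a secreted metabolic hormone, rose from 0.29 ± 0.151 to 3.11 ± 1.5 CPM. Herpud1 and Dnajc3, which act in endoplasmic reticulum protein quality control, fell, Herpud1 from 431 ± 108 to 37.6 ± 14 CPM.

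Camera called the NRF2 list (adjusted p = 1.09e-05), lost with an estimated correlation (adjusted p = 0.283), and not the stress response list (adjusted p = 0.206), which was called as higher without Mettl3-deficient replicate 3 (adjusted p = 0.000631). Stress response genes that rose numbered 1, 1 and 2 without wild type replicate 2, wild type replicate 3 and Mettl3-deficient replicate 1, 2 with limma-voom or without a filter on low counts, and 9 with library size alone, and 5 fell with the Y-linked covariate. NRF2 genes that fell numbered 4 with DESeq2 and 3 with the filter of CPM of at least 1.

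Fetal, cholangiocyte and immediate early genes were partly higher. Of 14 fetal liver and progenitor genes 7 rose and 0 fell (9 adjusted over the list alone), with Ly6d, Sox4 from 1.79 ± 0.533 to 9.3 ± 3.18 CPM (SD, n = 3; edgeR adjusted p = 0.00583), Rhou and alpha-fetoprotein (Afp), the latter pair higher by 3- and 2.84-fold. Of 15 cholangiocyte markers 7 rose and 0 fell (8 adjusted over the list alone), with Krt23 from 1.29 ± 0.465 to 17.2 ± 3.3 CPM and Ddr1 from 4.72 ± 1 to 42.9 ± 16.3 CPM. Of 18 YAP targets 4 rose and 0 fell (4 adjusted over the list alone), namely Tead1, Ajuba, Ccn1 and Birc5, the last also a cell cycle member. Of 16 immediate early genes 6 rose and 3 fell (9 and 3 adjusted over the list alone), with Klf6 and Ier3 higher by 3.18- and 5.38-fold and Dusp1 and Zfp36 lower by 4.1- and 2.16-fold.

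Camera called the fetal (adjusted p = 2.2e-05), cholangiocyte (adjusted p = 0.000135) and YAP (adjusted p = 0.03) lists and not the immediate early list (adjusted p = 0.063). The YAP call was lost without Mettl3-deficient replicate 3 (adjusted p = 0.106), and the immediate early list was called without that library (0.0191), without wild type replicate 3 (0.0436) and without a filter on low counts (0.0392). With an estimated correlation the first 3 had adjusted p = 0.155, 0.4 and 0.542. Fetal genes that rose numbered 3 without wild type replicate 2. Cholangiocyte markers that rose numbered 3 without wild type replicate 3, Mettl3-deficient replicate 1 or Mettl3-deficient replicate 3, and 4 without wild type replicate 2 or with limma-voom. Immediate early genes that rose numbered 2 without wild type replicate 2 or Mettl3-deficient replicate 1, 3 without wild type replicate 3 or Mettl3-deficient replicate 2, 2 with the Y-linked covariate and 10 with library size alone, which also gave 9 higher YAP targets.

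Markers of monocytes and recruited macrophages rose while those of resident cells mostly did not pass the test. Of 17 monocyte and macrophage markers 14 rose and 0 fell (17 adjusted over the list alone), with Gpnmb from 0.369 ± 0.138 to 10.7 ± 4.65 CPM (SD, n = 3; edgeR adjusted p = 0.00131), Cd9 from 13.6 ± 5.2 to 78.8 ± 2.06 CPM, and Mmp12 and Itgam higher by 27.4- and 4.06-fold. None of 14 Kupffer cell markers was called by edgeR, adjusted over all genes or over the list alone, with 0 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom, and Adgre1 and C1qa had log2 fold changes of 0.93 and 0.58. Of 16 endothelial markers 0 rose and 1 fell, Lyve1 (log2 fold change -1.28 ± 0.30), likewise adjusted over the list alone, and the list's median was -0.06, or 0.43 with library size alone. Of 24 stellate cell and fibrosis genes 2 rose, Timp1 and Lox, and 0 fell (2 adjusted over the list alone).

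Calls among blood cell markers were higher for neutrophil and for B and plasma cell markers, and lower for erythroid genes and Cd4. S100a9 and Csf3r rose among the 3 tested neutrophil markers (2 adjusted over the list alone), and Jchain and Igkc, which encode immunoglobulin chains, rose 2.95- and 3.49-fold among 11 B and plasma cell markers (2 adjusted over the list alone). Of 14 T and NK cell markers 0 rose and 1 fell, Cd4 (0 adjusted over the list alone). Of 6 erythroid genes 5 fell and 0 rose (5 adjusted over the list alone), with Hba-a1 from 26.3 ± 8.62 to 5.17 ± 1.75 CPM (SD, n = 3) and Tspan33, Klf1 and Hbb-bs lower by 2.73-, 3.01- and 6.16-fold. Of 5 pancreas and gut markers 0 rose and 1 fell, Cela1 (1 adjusted over the list alone), and the median of 1.01 and the mean of -0.07 of that list differed in sign.

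Camera called the monocyte (adjusted p = 8.05e-11) and erythroid (adjusted p = 3.67e-05) lists, with adjusted p = 0.0972 and 0.155 with an estimated correlation, and none of the other lists of cell types apart from cholangiocytes. The stellate list was called with limma-voom (adjusted p = 0.0498), without a filter on low counts (0.0384), with the Y-linked covariate (0.00202) and without Mettl3-deficient replicate 1 (0.0371) or 2 (0.00393), the Kupffer list without wild type replicate 3 (0.0247), and the endothelial list, as lower, without wild type replicate 1 (0.041). Monocyte markers that rose numbered 8, 8 and 9 without wild type replicate 2, wild type replicate 3 and Mettl3-deficient replicate 1, and erythroid genes that fell 3, 2 and 3 without wild type replicate 3, Mettl3-deficient replicate 1 and Mettl3-deficient replicate 2, and 3 with limma-voom. The calls of Lyve1, Cd4, Cela1, S100a9, Csf3r, Jchain, Igkc and Lox were each lost in at least 1 fit that left out a library, Mettl3-deficient replicate 1 among them for each. Stellate genes that rose numbered 10 with library size alone, 9 with the Y-linked covariate and 4 with DESeq2 or without wild type replicate 1, and 4 endothelial markers fell without wild type replicate 1. With library size alone 3 endothelial, 3 Kupffer cell, 3 T and NK cell and 4 B and plasma cell markers rose.

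Interferon response genes were partly higher and acute phase genes went both ways. Of 25 interferon genes 7 rose and 0 fell (7 adjusted over the list alone), with Zbp1, a nucleic acid sensor, from 5.95 ± 0.649 to 37 ± 21.8 CPM (SD, n = 3; edgeR adjusted p = 0.00705), and Usp18, Ifit2 and Ifi27l2a higher by 2.65-, 3.37- and 2.33-fold. Of 21 acute phase and cytokine genes 3 rose and 3 fell (3 and 4 adjusted over the list alone). Il1rn, the interleukin-1 receptor antagonist, and the monocyte chemokine Ccl2 rose 3.56- and 6.26-fold, and Nfkbia and Il1r1 fell 1.85- and 2.07-fold.

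Camera called the interferon list (adjusted p = 0.000826), lost with an estimated correlation (adjusted p = 0.568), and not the acute phase list (adjusted p = 0.782), whose median of -0.19 and mean of 0.06 differed in sign. Interferon genes that rose numbered 3 without wild type replicate 2, wild type replicate 3, Mettl3-deficient replicate 1 or Mettl3-deficient replicate 2, and 12 without wild type replicate 1 or Mettl3-deficient replicate 3 or with library size alone. No acute phase gene fell (0 of 21 by edgeR) without wild type replicate 2, wild type replicate 3 or Mettl3-deficient replicate 2, or with library size alone. With DESeq2 7 fell, and 1 rose without wild type replicate 2 or 3 or Mettl3-deficient replicate 1 or 2.

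**Figure D2:**
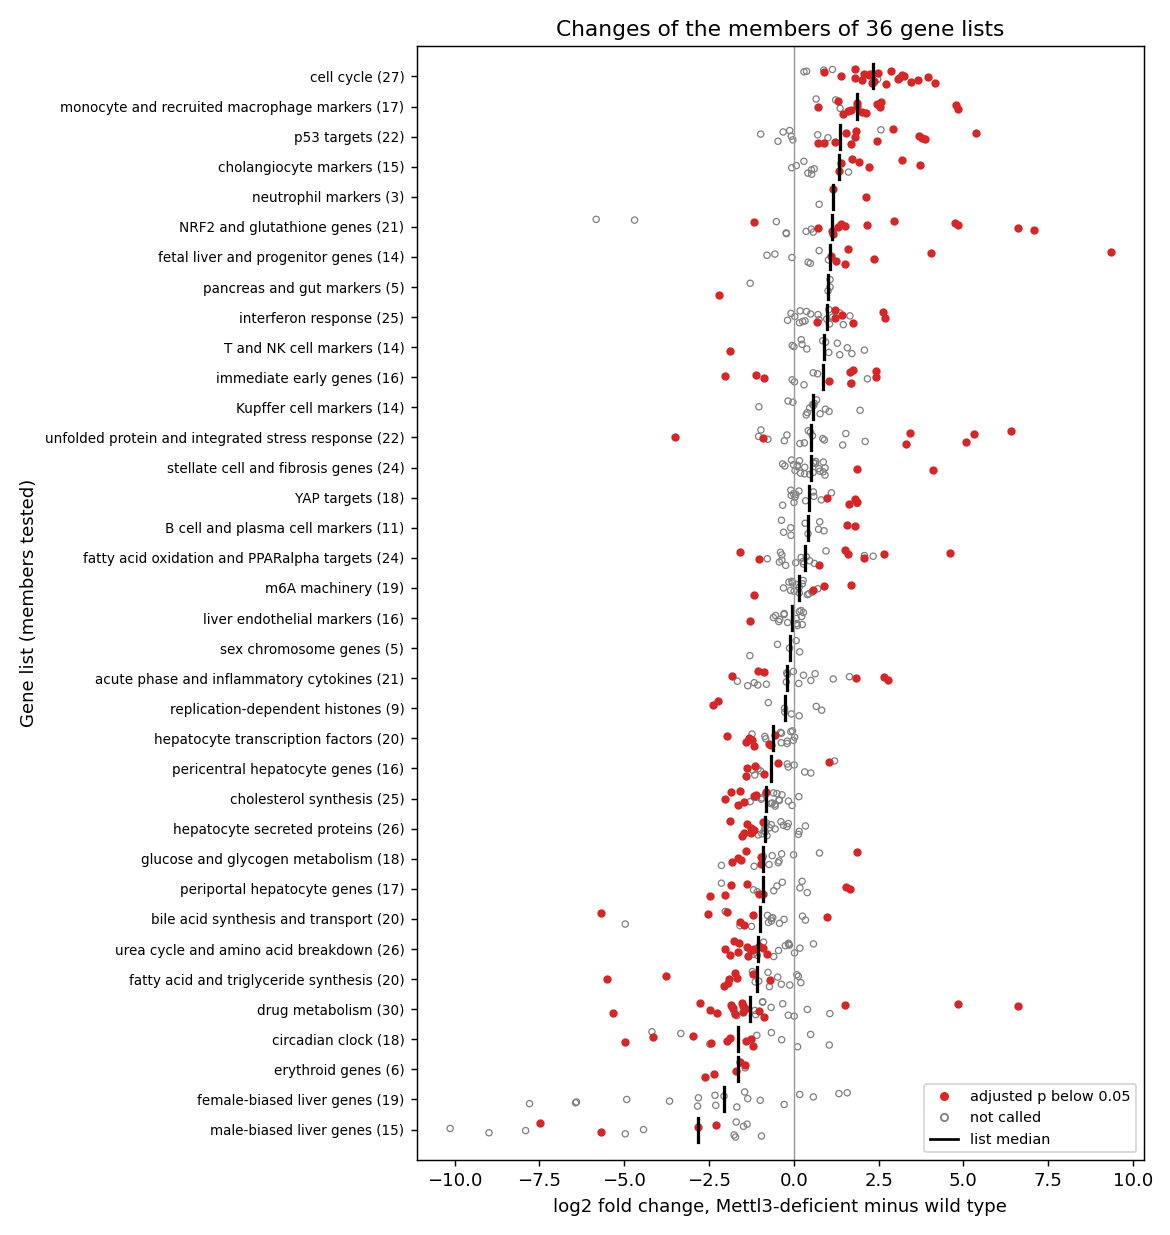
The log2 fold change (Mettl3-deficient minus wild type) of each tested member of the 36 gene lists, with the number of members tested in parentheses, red points for genes with an adjusted p under 0.05, open points for the rest and black bars for list medians. Cell cycle, with a median of 2.34, lies at the top and male-biased genes, with a median of -2.84, lie at the bottom (-1.20 without wild type replicate 1).

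Some clock genes were lower in Mettl3-deficient livers, and clock genes also differed among wild-type livers. Of 18 clock genes 9 fell and 0 rose (12 fell adjusted over the list alone). Cry1, a repressor of the clock, fell from 42.3 ± 10.2 to 10.7 ± 2.7 CPM (SD, n = 3; edgeR adjusted p = 0.00367), Per2 from 64.2 ± 31.3 to 11.9 ± 2.3 CPM, and Cry2 and Clock fell 2.65- and 2.32-fold. Wild type replicate 1 held 2.98 CPM of Per1 against 75.7 and 74.3 CPM in the other wild-type livers, and 13.99 CPM of Npas2 against 0.14 and 0.30 CPM. The list's median was -1.64, with a camera adjusted p of 2.79e-05 that was lost with an estimated correlation (adjusted p = 0.26). Clock genes that fell numbered 5, 5, 4 and 4 without wild type replicate 2, wild type replicate 3, Mettl3-deficient replicate 1 and Mettl3-deficient replicate 2, and 2 rose without wild type replicate 1. The call of Clock was lost without Mettl3-deficient replicate 1 and with library size alone.

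Some male-biased liver genes were lower, and female-biased genes were not called in the comparison of all 6 libraries. Of 15 male-biased genes 4 fell and 0 rose (5 fell adjusted over the list alone). Slco1a1, an organic anion transporter, fell from 444 ± 436 to 8.6 ± 5.42 CPM (SD, n = 3; edgeR adjusted p = 0.0091), Serpina1e from 6983 ± 4431 to 39.3 ± 9.77 CPM, and Selenbp2 and Ugt2b38 fell 7.14- and 4.87-fold. None of 19 female-biased genes was called by edgeR, adjusted over all genes or over the list alone, with 4 at an unadjusted p under 0.05, 5 called by DESeq2 and 0 by limma-voom, and Fmo2, Cyp3a44, Cyp3a41a and Cyp3a41b had log2 fold changes of -1.36, -6.41, -7.79 and -6.44.

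Without wild type replicate 1, 14 of the 20 female-biased genes tested in that fit fell and 1 rose, but 0 of the wild-type and 2 of the 3 Mettl3-deficient libraries of that fit carried Y-linked transcripts, so genotype and sex were mixed there. Male-biased genes that fell numbered 8 with the Y-linked covariate, and 2 without Mettl3-deficient replicate 2 or 3 or without a filter on low counts. Camera called the male-biased list (adjusted p = 0.000108), lost with an estimated correlation (adjusted p = 0.542), and not the female-biased list (adjusted p = 0.343), which was called as lower without wild type replicate 1 (7.12e-19) and with library size alone (0.00869). The male-biased median was -2.84, and -1.20 without wild type replicate 1. None of the 5 sex chromosome genes was called by edgeR, adjusted over all genes or over the list alone, by DESeq2 or by limma-voom, with 0 at an unadjusted p under 0.05 and log2 fold changes of -1.30 for Xist, -0.48 for Kdm5d, 0.17 for Ddx3y, -0.13 for Eif2s3y and 0.07 for Uty.

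**Figure D3:**
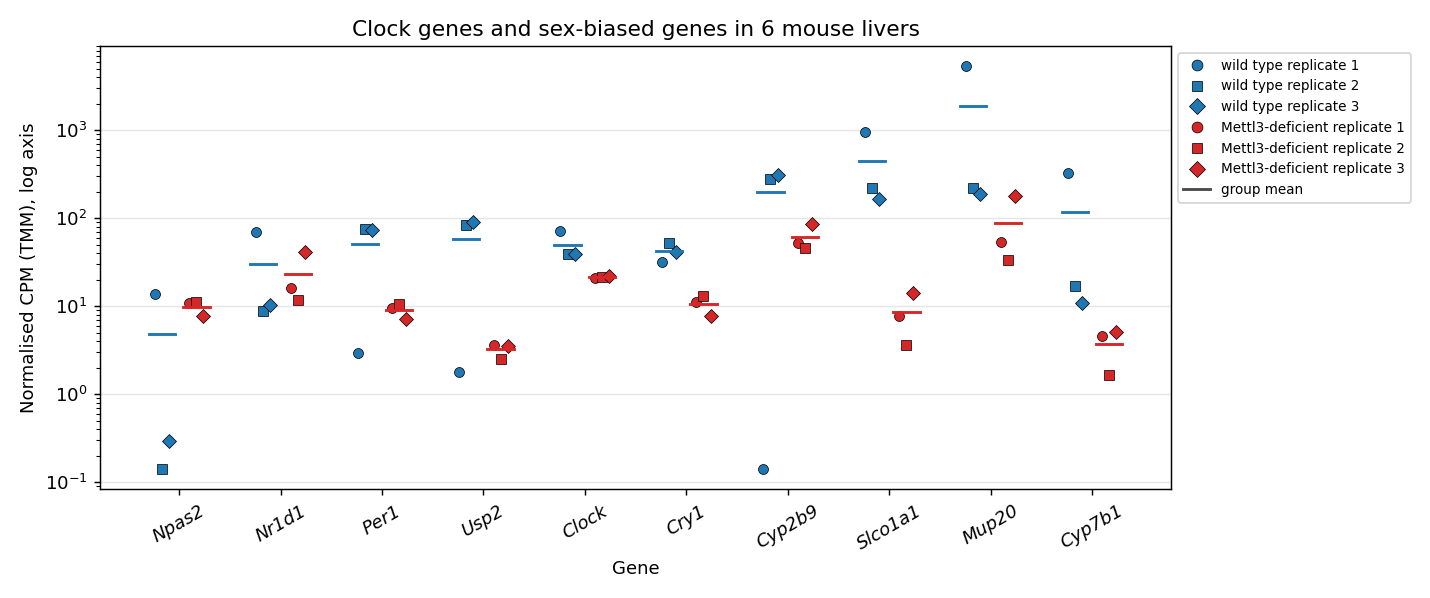
Normalised CPM (TMM, log axis) of 6 clock genes and 4 sex-biased genes in each of the 6 livers, with blue for wild type, red for Mettl3-deficient, symbols for replicates and bars for group means. Wild type replicate 1, the blue circle, lies apart from the other wild-type livers for Per1 (2.98 against 75.7 and 74.3 CPM).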

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

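The tests of sex-biased and clock genes in this part were chosen after the results were seen, and the tests of other splits of the samples were planned before.

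The genotype difference was not alike in libraries with and without Y-linked transcripts for 160 genes, by an edgeR interaction term at an adjusted p under 0.05. The fit had 2 residual degrees of freedom, and wild type with Y-linked transcripts and Mettl3-deficient without them were 1 library each, so a difference by Y cannot be separated from those 2 animals; 2901 genes had an unadjusted p under 0.05. Of the 160, 10 were among the 19 female-biased and 2 among the 15 male-biased genes. Cyp2b9 held 0.142 CPM in wild type replicate 1, 282 and 310 CPM in the other wild-type livers, and 52.5, 46.0 and 86.0 CPM in the Mettl3-deficient livers.

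In wild-type livers, the library with Y-linked transcripts differed from those without by a median log2 difference of -8.03 in female-biased genes and 3.67 in male-biased genes. In Mettl3-deficient livers these differences were -0.76 and 0.30, and female-biased genes of the Mettl3-deficient liver without Y stood at a median of 19.7% of wild type without Y, a comparison without wild type replicate 1 that rests on 1 Mettl3-deficient library. Mixed male and female tissue is argued against, since Xist in the Y-carrying Mettl3-deficient livers was 0.142% of its level in the other one, while female-biased genes stood at a median of 16.6% of wild type without Y. An unequal number of Y-carrying livers, 2 against 1, would raise male-biased genes, but their median was -2.84 (-1.20 without wild type replicate 1, the wild-type library with Y) and 15 of 15 lay below 0. With 1 wild-type library carrying Y and 1 Mettl3-deficient library without it, it cannot be told apart whether wild type replicate 1 was unusual for its sex or sex-biased expression may be smaller in Mettl3-deficient livers, and wild type replicate 1 also stood apart in its clock genes.

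The 18 clock genes of wild type replicate 1 differed from the other wild-type livers by a median absolute log2 difference of 1.87, above each of 10000 random lists matched on expression, whose median was 0.316. Of the 9 clock genes that fell, 8 had lower values in each Mettl3-deficient liver than in each wild-type liver, which chance gives, in either direction, in 10% of unselected genes, but 3406 of the 3420 called genes were separated in this way, so the test could hardly have come out otherwise. It says nothing on collection at the hour of wild type replicate 1, for which 1 library would stand in any case, and the rule that at least 2 wild-type libraries must do so was added after the values were known (before it, these 8 genes counted against this explanation). For an hour that no wild-type liver shares, genes in antiphase to Dbp could rise. Arntl, Npas2, Clock and Nfil3 had a median of 0.302, but went both ways, with Clock lower and called and none called higher. Wild type replicate 1 held 37.79 CPM of Arntl against 22.07 and 11.09 CPM, so the wild-type mean mixes unlike livers and cannot decide this. Against wild type replicates 2 and 3 alone, Arntl, Npas2 and Nfil3 were higher in each Mettl3-deficient liver, and Clock was lower. The bound for these genes was first a median above 0.3, which 0.302 passed, so at first these genes counted for this explanation. It was tightened to ask also for 3 of the 4 called higher after the values were known. Because the wild-type livers were unlike, collection time and genotype cannot be told apart here under either bound. The hour of collection is not given in the sources used here.

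With the 10 possible splits of the 6 libraries into 3 and 3, no share under 0.05 can be reached. The real split called 3420 genes (1906 higher, 1514 lower, 2139 over 2-fold), and 1 of the 10 splits, the real one, gave as many for each of these counts. The highest of the other splits called 0 genes by edgeR and by limma-voom, 166 by DESeq2, and 994 at an unadjusted p under 0.05. For gene lists called by camera, the real split gave 20 and the highest other split 22, the one that follows Y-linked transcripts, and 4 of the 10 splits gave 20 or more. The lowest of the other splits still gave 12 lists, with 0 genes called by edgeR. The number of lists called by camera therefore does not set the genotype split apart from other groupings of these livers.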

How the results depend on the processing

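Library size alone and the Y-linked covariate were chosen after seeing the data. Mettl3 was lower and called in every alternative run, with log2 fold changes from -1.28 to -0.70. The same 995 genes (656 higher, 339 lower) were called in one direction in all of them. Genes called ranged from 1382 to 3514 over the fits that left out 1 library, genes higher from 840 to 1932, genes lower from 518 to 1582 and those over 2-fold from 1204 to 2351, with the low values without wild type replicates 2 and 3 and Mettl3-deficient replicates 1 and 2. Library size alone gave 5405 called, 4810 higher, 595 lower and 3457 over 2-fold. The shared shift of 0.49 in the median of all genes shows in that split. The other alternatives gave 3192 to 3419 genes, except DESeq2 with 4575, the Y-linked covariate with 3244 (2854 of the main calls shared) and the block below. Gene lists called by camera numbered 20 to 24 over the same fits, 0 with an estimated correlation and 13 with fry (direction). The cause was not tested.

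Replicate numbers did not pair the samples: correlations of same-numbered deviations were 0.084, -0.017 and 0.034, and not every sample correlated best with its own number. With the replicate block 2683 genes were called, 1528 higher, 1155 lower and 1863 over 2-fold, Mettl3 was -1.19 and 21 lists passed camera.

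Results that changed sign were mostly not called. Rbm15b was -0.0053 with RLE, -0.0052 with DESeq2, -0.0020 with the replicate block, -0.069 with the Y-linked covariate and -0.12 to 0.18 over fits that left out 1 library. Igf2bp3 was 0.70 with limma-voom, 0.53 with the block, 0.44 with library size alone, 1.17 with the covariate and -0.59 to 0.72 over the fits with 1 library left out. Library size alone gave Zc3h13 0.38, Alkbh5 0.17, Ythdc2 0.45, Igf2bp2 0.33, Stab2 0.039, Clec4g 0.070, Eif2s3y 0.33 and the sex chromosome list 0.33. With 1 library left out, Ythdc2 ran from -0.23 to 0.08 and Igf2bp2 from -0.38 to 0.11.

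Kdm5d was 2.44 with limma-voom and 1.64 with the block, and Eif2s3y 3.25 and 2.51. With the covariate Xist was 0.065, Ddx3y -0.82 (edgeR adjusted p = 0.0447) and Uty -0.92. With 1 library left out, Kdm5d ran from -1.19 to 10.86, Eif2s3y from -0.72 to 12.91, Ddx3y from -0.42 to 13.34 and Uty from -0.55 to 11.03, and the sex chromosome list was 11.03 without wild type replicate 1 and 0.46 without Mettl3-deficient replicate 3, 2.68 with limma-voom and 2.10 with the block. The Y-linked genes had 0 counts in the libraries without Y. The female-biased median was 0.39 with the covariate, and the acute phase median 0.076 with the covariate, 0.32 with library size alone and 0.022 without wild type replicate 2. The histone median was 0.19 with library size alone, 0.37 without a filter and 0.14 without wild type replicate 1, and the endothelial median 0.43 with library size alone, 0.095 with the covariate and 0.12 without wild type replicate 3. The pancreas and gut median ran from -0.14 to 1.26 over fits with 1 library left out. In other cases the direction given by camera turned while the median kept its sign, namely for the female-biased list with limma-voom (median -0.17), the pancreas and gut list without a filter (1.08) or without Mettl3-deficient replicate 2 (1.17), the sex chromosome list with the covariate (-0.92) and without wild type replicate 2 (-0.71), wild type replicate 3 (-0.641), Mettl3-deficient replicate 1 (-0.649) or Mettl3-deficient replicate 2 (-0.38), and the Kupffer list without wild type replicate 1 (0.25, in a range from 0.25 to 0.82 over fits with 1 library left out). The cause of each was not tested. Changes near 2-fold were often missed in the simulated counts, where few genes were changed.

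Other genes named for the lists lost their call in the following fits that left out 1 library: Ccl2, Dnajc3, Gulo, Hnf4a, Ifi27l2a, Lect2, Nfkbia and Nr1h4 without wild type replicate 2 or 3 or Mettl3-deficient replicate 1 or 2; Birc5, Cidec, F9, Klf1, Otc and Pklr without Mettl3-deficient replicate 1; Abcg8, Fgb, Glul, Gys2 and Hal without wild type replicate 2 or 3 or Mettl3-deficient replicate 1; Cebpa, Gnmt and Rbp4 without wild type replicate 2 or Mettl3-deficient replicate 1; Cyp27a1, Igf1 and Zfp36 without wild type replicate 2 or 3; Etnppl and Idi1 without wild type replicate 2 or 3 or Mettl3-deficient replicate 2; Afp without wild type replicate 2; Ccn1 without wild type replicate 3; Hbb-bs without wild type replicate 3 or Mettl3-deficient replicate 1 or 2; Il1r1 without wild type replicate 2 or 3 or Mettl3-deficient replicate 1, 2 or 3; Insig1 without wild type replicate 1, 2 or 3 or Mettl3-deficient replicate 2; Sds without wild type replicate 2 or Mettl3-deficient replicate 1 or 2; Selenbp2 without wild type replicate 3 or Mettl3-deficient replicate 2 or 3; Ugt2b38 without Mettl3-deficient replicate 1, 2 or 3.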

Other observations

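The gene families in the first paragraphs and the test of the hepatocyte share were chosen after values were seen. The test of long internal exons was written before its own values were seen. Its rule divides the libraries by Y-linked transcripts, which the labels do not give, so it was not fixed before the data were examined. Of 41 families defined by gene name that were looked at, 11 are described here, picked for their values, and none was tested for enrichment.

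Of 10 tubulin genes 6 rose and 0 fell. Tubb6 rose from 15.2 to 58.1 CPM (log2 fold change 1.94 ± 0.38, edgeR adjusted p = 0.0133) and Tubb5 from 12.3 to 56.0 CPM. Tubb6 and Tuba8, another tubulin that rose, were among the 160 genes whose genotype difference was not alike in libraries with and without Y-linked transcripts. So were other genes named above, among them Per2, Ajuba, Atf3, Mt1 and Mt2. Among 11 annexins 5 rose and 0 fell, with Anxa2 from 14.5 to 97.9 CPM (log2 fold change 2.76 ± 0.24, edgeR adjusted p = 0.000954) and Anxa5 from 49.9 to 172 CPM. Of 12 immunoglobulin genes 7 rose and 0 fell, with Igha from 1.99 to 19.3 CPM. Of 15 host genes of small nucleolar RNAs 7 rose and 0 fell, with Snhg15 from 2.63 to 9.92 CPM. With library size alone 8 tubulins, 8 annexins, 10 immunoglobulin genes and 12 of these host genes rose.

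Several enzyme families and Serpina genes held more lower than higher calls, and glutathione transferases went both ways. Of 13 UDP-glucuronosyltransferases 7 fell and 0 rose (4 and 1 with library size alone), with Ugt2a3 from 320 to 66.6 CPM (log2 fold change -2.27 ± 0.34, edgeR adjusted p = 0.00583). Of 11 sulfotransferases 5 fell and 1 rose, with Sult2a8 from 926 to 13.5 CPM. Of 20 glutathione transferases 7 rose and 3 fell, with a median of -0.01 that was 0.45 with library size alone. Of 74 cytochromes P450 25 fell and 4 rose (19 and 7 with library size alone), and of 20 Serpina genes 11 fell and 2 rose (11 and 4 with library size alone), with Serpina3k from 8437 to 1138 CPM, although copies of this family can share reads. Of 39 genes named as subunits of complex I of the respiratory chain 11 fell and 0 rose, with a median of -0.41 that turned to 0.07 with library size alone, where 0 fell and 3 rose. Cytosolic ribosomal protein genes gave 1 higher and 0 lower of 72, and 35 higher with library size alone.

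Lower hepatocyte lists with higher monocyte markers would follow from a lower share of hepatocytes if markers of other cell types rose alike. Over 8 lists of other cell types the medians were 1.86 for monocytes, 1.33 for cholangiocytes, 1.15 for neutrophils (3 genes, and 1.802 without wild type replicate 3), 0.89 for T and NK cells (0.48 without wild type replicate 1), 0.57 for Kupffer cells (0.25 and 0.29 without wild type replicate 1 and Mettl3-deficient replicate 2), 0.52 for stellate cells (0.11 without Mettl3-deficient replicate 3), 0.42 for B and plasma cells (0.71 and 0.65 without wild type replicate 3 and Mettl3-deficient replicate 1) and -0.06 for endothelial cells (from -0.27 without wild type replicate 1 to 0.12 without wild type replicate 3, with 0.10 with the Y-linked covariate and 0.43 with library size alone). The highest and lowest were 1.92 apart on the log2 scale (permutation p = 0.019 over the genes of the 8 lists, which are not independent). The monocyte minus endothelial difference per library, against wild-type means, was 0.63, -0.02 and -0.30 in wild-type and 1.77, 1.87 and 1.77 in Mettl3-deficient livers. This pair was picked as the highest and lowest median of the same libraries, so its separation was largely fixed by that choice. But lists also moved apart between wild-type livers. Against wild-type means, the Kupffer cell median was -1.09, 0.48 and 0.67 in wild type replicates 1, 2 and 3. The B and plasma cell median was 0.25, -0.20 and -0.04 in the same libraries. So the spread of the medians cannot decide whether a lower hepatocyte share was the whole cause. Of the 8 medians, 7 lay above 0, as a lower share would give, so a lower share may be a part. More monocytes or a change within hepatocytes may remain, all untested.

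Long internal exons are a feature of many m6A-bearing transcripts, and a candidate effect of Mettl3 loss is that such transcripts are higher. Among 13097 annotated genes, the 2754 with an internal exon of at least 400 bases had a log2 fold change higher by 0.0658 than other genes of the same length decile (permutation p = 0.043 over genes, which are not independent). The difference was 0.175 in libraries with Y-linked transcripts and 0.056 in those without. The first rests on 1 wild-type library and the second on 1 Mettl3-deficient library, so neither can be separated from that animal. The test asked for a permutation p under 0.05 in both, which was reached in the first only, so it stays undecided. Of called genes with such an exon 66.1% were higher, against 54.6% of the others, without matching on length and without a test. Such shares depend on scaling, since 55.7% of all calls were higher with TMM and 89.0% with library size alone. The level of m6A itself was not measured.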
